A study of Mus musculus with 2 samples.

How the data were processed

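In all, 2 libraries were analysed, 1 of MHCII-positive and 1 of MHCII-negative macrophages, grouped by the sample labels. Both were made with a 10x 3′ chemistry kit, per the labels' protocols. Counts per gene and cell are deposited as raw UMI counts, made with Cell Ranger 7.0.0 on the mm10 build, per the submitters' processing notes. Whether intronic reads were counted and the annotation release are not given in the sources used here. The sort had a purity above 90%, per the labels' protocols. The files hold 32285 features. Coordinates were taken from GENCODE M21 (GRCm38), where 32158 feature IDs matched and 31436 had the same symbol. Where 2 features share a symbol, the one with more UMIs was used.

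Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrial genes were kept, 87.3% of MHCII-positive and 95.9% of MHCII-negative barcodes. Scrublet, run in scanpy 1.11.5 at expected rates of 24.8% and 5.37%, did not work with its automatic threshold. It marked 27062 of 27091 MHCII-positive cells (99.9%) and 2 of 6441 MHCII-negative cells (0.0311%). The plan was to remove marked cells unless fewer than 0.5% were marked. A first run removed marked cells in both libraries, although that clause should have kept them in the MHCII-negative one. It left 29 and 6439 cells and was discarded. An upper limit of 50% was then added, after the data were seen, so that no cell was removed as a doublet in either library. Doublets therefore remain in all values.

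The kept cells were clustered together, after scaling to 10000 counts per cell and log transformation, on 2000 variable genes without MHC class II genes, among genes found in at least 10 cells. The settings were 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2). Marker genes of each class were fixed before the data were examined. The rule that turns markers into class names, with its limits, was set after looking at the clusters. A class other than macrophage needed a mean log2 fold of at least 1 over the median of the other clusters and at least 3 markers raised 2-fold at 10 CPM or more. Macrophage-like clusters needed at least 3 markers at 50 CPM. The check on the 10 leading genes of each cluster was run in 2 versions. In the first, against the median of the other clusters, cluster 0 (8742 MHCII-positive and 10 MHCII-negative cells) had more markers of another class than of its own, and cluster 20 was named macrophage-like. The reference was then changed to the mean of the other clusters, under which no macrophage-like cluster failed and cluster 20 stayed unnamed (3 MHCII-positive and 51 MHCII-negative cells, 0.0111% and 0.792%). Under the mean, cluster 21 of the T cell or T lymphoma-like class had 0 own markers and 1 mast cell marker, Cma1, among its leading genes, so that class is not compared between the libraries by name. Under the median cluster 21 had 2 own markers, Trbc2 and Cd3d, and 1 mast cell marker. The mean is the version used. Because it was chosen with both outcomes known, the comparisons were also run without cluster 0.

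For the comparison, raw UMI counts of macrophage-like cells were summed per library, 25976 and 6017 cells, and expressed as CPM. No test was made, since each group has 1 library. Log2 ratios carry exact conditional binomial 95% intervals (scipy 1.17.1) that cover counting error only. Genes with a mean of at least 5 CPM were compared, and a gene was called higher at 1.5-fold or more with an interval excluding equality. A count of 0 was set to 3 counts. For 24 gene lists fixed before the data were examined, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries. On simulated counts with the real means and library sizes, 50 of 50 genes changed 2-fold, 50 of 50 changed 4-fold and 26 of 50 changed 1.5-fold, exactly the limit, were recovered among 9194 genes. Of 9044 unchanged genes 0 were called, and 95.2% of true ratios lay inside their interval. These simulations hold counting error alone.

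Named genes followed a rule fixed before the data were examined. It takes 24 genes of interest, the 12 genes with the largest ratio in each direction at 50 CPM or more (without MHC class II, mitochondrial, ribosomal, unnamed, receptor segment and other-class marker genes), and from each list the 2 members with the largest ratio at 20 CPM or more and the 1 with the highest mean. It gave 92 genes, of which some are not reported here. Cells were thinned without replacement to 2000 UMIs for shares of cells with a UMI, with 1000, 4000 and no thinning as alternatives, and shares have exact binomial intervals. Values within clusters used clusters with at least 100 cells of each library. Depth was also compared within each library, between cells of 2000 to 4000 UMIs and cells of 8000 or more, a comparison added after the data were seen. Alternatives covered the cell filter, doublet scores, cells compared, scaling (the TMM factor from edgeR 4.0.16), depth, weights, size rule, expression floor and clustering. Free RNA was not removed from the counts. It was described by macrophage transcripts in T cell-like, NK cell-like and neutrophil-like cells, which may also come from doublets. The T cell or T lymphoma-like class was the background planned for shares. Its clusters were taken apart after the data were seen.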

Results

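Single-cell RNA sequencing was done on macrophages sorted from tumours of the mouse T lymphoma line RMA that lacks Qa-1b, a non-classical MHC class I molecule. The tumours were regressing in wild-type mice after therapeutic vaccination, given when tumours measured 10 to 50 mm3. Live CD45+ CD11b+ F4/80+ cells were sorted into an MHC class II-positive and an MHC class II-negative fraction, and each fraction gave 1 library. The MHCII-positive library held 31029 barcodes with 122711153 unique molecular identifiers (UMIs, each standing for 1 captured transcript). The MHCII-negative library held 6717 barcodes with 71509047 UMIs. After filtering, 27091 MHCII-positive cells with a median of 2836 UMIs and 6441 MHCII-negative cells with a median of 10184 UMIs were left. Because the libraries differ in depth, values in cells of 2000 to 4000 UMIs (8031 and 608 macrophage-like cells, a setting chosen after the data were seen, here called shallow cells) are given where they change a result. They do not compare the same kinds of cells at equal depth, since 337 of the 608 MHCII-negative cells (55.4%) were of cluster 9 and their median mitochondrial share was 4.06%, against 1.64% in all MHCII-negative macrophage-like cells. With 1 library per group, no difference has a replicate check and none was tested. Every interval is a 95% interval that covers counting error only, and "higher" means a ratio of at least 1.5-fold whose counting interval excludes equality.

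Monocyte/macrophage-like cells, here called macrophage-like, made up nearly all of both sorted fractions. They were 25976 of 27091 MHCII-positive cells (95.9%, exact binomial interval 95.6 to 96.1) and 6017 of 6441 MHCII-negative cells (93.4%, 92.8 to 94.0). Every cluster met the limit of 3 macrophage markers at 50 CPM, from 8 markers in cluster 21 to 24 in cluster 13. These shares therefore count cells neither given another class nor left unnamed, and do not separate monocytes from macrophages. Neutrophil-like cells were 222 of 6441 MHCII-negative cells (3.45%, 3.01 to 3.92) and 0 of 27091 MHCII-positive cells, which allows a share of up to 0.0111%. Dendritic cell-like cells were 295 MHCII-positive cells (1.09%, 0.969 to 1.22) and 9 MHCII-negative cells (0.140%, 0.0639 to 0.265), a class whose MHC class II protein the gate selects. Clusters 13 and 15, with haemoglobin and T lineage genes over a macrophage profile, were kept out of the macrophage-like class by a rule set after the data were seen and held 1.16% and 0.845% of MHCII-positive and 0.0155% and 0.155% of MHCII-negative cells. The sort gate sets which classes can appear, and the share of monocyte/macrophage-like cells, MHCII-negative, moved between 82.8% and 95.01% with the clustering and filter settings. Most MHCII-positive macrophage-like cells lay in clusters 0, 1, 2, 3, 4 and 7, and most MHCII-negative ones in clusters 5, 6, 8 and 9, so a cluster mostly of 1 library may stand for that library. The macrophage-like class met the condition for a comparison with leading genes taken against the mean of the other clusters. Against their median, which was run first, cluster 0 had 0 macrophage markers and 1 erythroid marker, Hbb-bs, among its 10 leading genes, so counts without cluster 0 are given beside the main ones.

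MHC class II transcripts followed the sort. H2-Aa, H2-Ab1 and H2-Eb1, which encode MHC class II chains, stood at 4459, 3735 and 3552 CPM (UMI counts of a gene scaled to a common library total) in MHCII-positive macrophage-like cells and at 517, 533 and 273 CPM in MHCII-negative ones. Their log2 ratios, MHCII-positive over MHCII-negative, were 3.11, 2.81 and 3.70. Cd74, the invariant chain, was at 8739 and 2142 CPM (log2 ratio 2.03, 2.02 to 2.04). Of 8 measured genes of the MHC class II list 6 were higher in the MHCII-positive library, with a median log2 ratio of 1.88. H2-Ab1 lies on chromosome 17, positions 34257689 to 34269419 of GRCm38 (mm10), and is annotated as protein coding. MHC class I genes differed less. Of 18 measured members 5 were higher in the MHCII-positive library and 1 in the MHCII-negative library, with H2-K1 at 2063 and 1166 CPM, Calr (0.68) among the 5, and B2m at 3739 and 2582 CPM within 1.5-fold, though past it with TMM scaling (0.77) and in shallow cells (0.70). H2-K1 and Calr came inside 1.5-fold, at 0.51 and 0.16, when each of the 5 clusters shared by both libraries had equal weight, and H2-K1 was at 0.087 in shallow cells.

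The main comparison asks how MHCII-positive and MHCII-negative macrophages of a regressing tumour differ. Most complement, chemokine ligand and mature macrophage genes were higher in MHCII-positive cells, and most monocyte genes were higher in MHCII-negative cells. C1qa, C1qb and C1qc, the chains of complement C1q, had log2 ratios of 4.96, 4.39 and 4.43, and C1qa was at 1249 CPM in MHCII-positive and 40.0 CPM in MHCII-negative cells. Ccl8, a monocyte-attracting chemokine, had the largest ratio toward MHCII-positive cells among the genes taken by the naming rule, at 348 and 4.47 CPM (log2 ratio 6.28, 6.12 to 6.45). In shallow cells Ccl8 was at 322 and 64.4 CPM (2.32), below C1qa at 1064 and 18.01 CPM (5.88). In the other direction Mmp8 (-6.29), Pglyrp1 (-6.17), Cd177 (-5.59), Hpgd (-5.53) and the fractalkine receptor gene Cx3cr1 (-5.08) were higher in MHCII-negative cells. Of 9204 genes with a mean of at least 5 CPM, 964 were higher in the MHCII-positive and 1672 in the MHCII-negative library, and 6568 lay within the rule. The median gene had a log2 ratio of -0.14. TMM scaling moved it to 0.094 and the split to 1720 and 946, a share higher in the MHCII-positive library of 64.5% in place of 36.6%, so the balance of the counts has no firm side. Without cluster 0 the counts were 972 and 1657. In shallow cells, which differ in more than depth, they were 1875 and 3449, with 726 and 1448 of the genes above among them, 11 in the opposite direction and the median gene at -0.31.

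**Figure D1:**
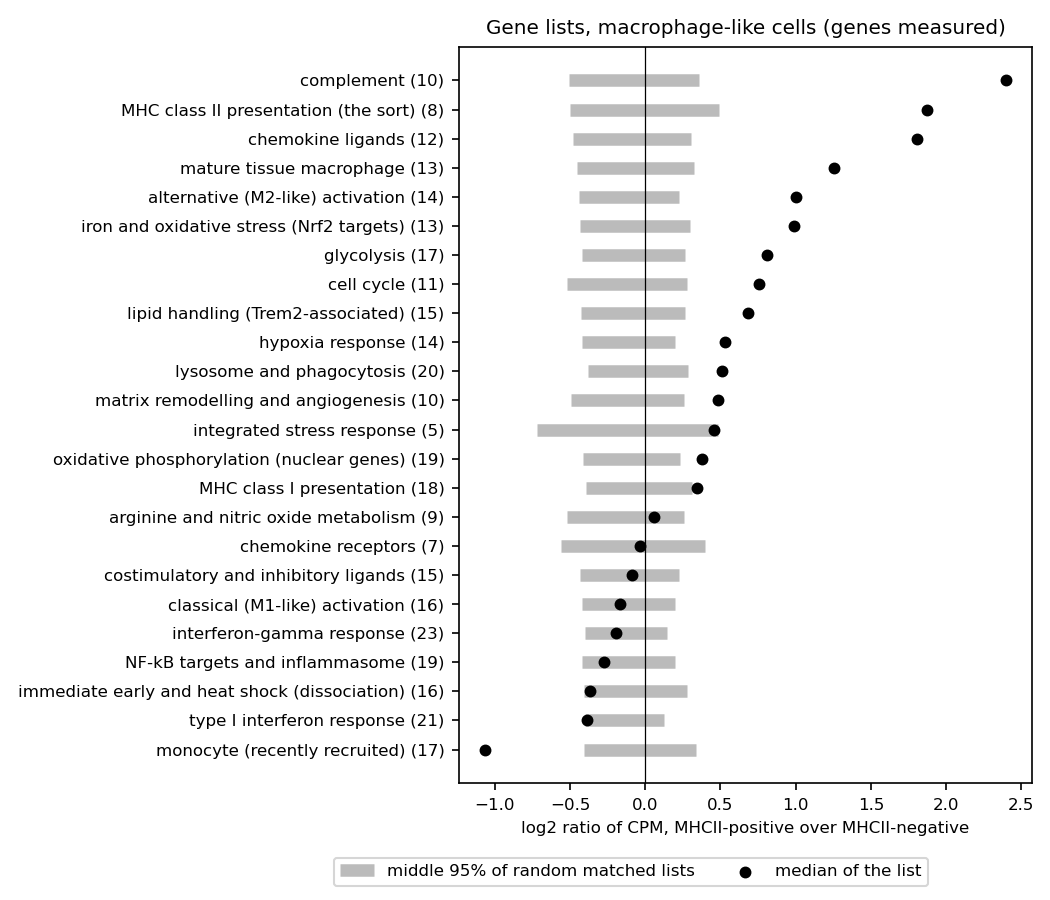
Median log2 ratio of CPM (MHCII-positive over MHCII-negative, x axis) of each gene list (y axis, number of genes measured in brackets) in macrophage-like cells, with grey bars for the middle 95% of 10000 random lists matched on size and mean expression. Complement (2.40) lies highest and the monocyte list (-1.06) lowest.

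Complement was the list with the highest median over the whole class, 2.40, above all 10000 random lists of the same size matched on expression. In it 8 of 10 measured genes were higher in MHCII-positive cells and 1 in MHCII-negative cells. Among chemokine ligands 11 of 12 were higher in MHCII-positive cells (median 1.81), including Ccl5 at 307 and 35.7 CPM and Ccl6 at 3299 and 1109 CPM. Genes of mature tissue macrophages had a median of 1.25, with 9 of 13 higher in MHCII-positive cells, among them Ms4a7 (3.03), Maf (1.71) and Adgre1, which encodes F4/80 (1.06), while Hpgd went the other way. With equal weight per shared cluster the complement median was 1.08, below MHC class II at 1.96, the chemokine ligand median 1.02, the mature macrophage median 0.56, inside 1.5-fold, and the lysosome and lipid medians 0.30 and 0.42. In shallow cells complement was at 1.92, below chemokine ligands at 2.26, and mature macrophage genes at 1.75. In the lysosome and phagocytosis list (median 0.51) 10 of 20 were higher in MHCII-positive cells, such as the protease gene Ctsd (2.37) and the apoptotic cell receptor gene Mertk (3.61), and Psap (0.38, and 0.61 with TMM scaling) lay within 1.5-fold. The lipid list had a median of 0.68, with 8 of 15 higher in MHCII-positive cells and 3 in MHCII-negative cells. Its members included Lpl, lipoprotein lipase, at 1291 and 215 CPM, Cd63 at 48.6 and 6.13 CPM and Lgals3 (0.68). Other genes with large ratios toward MHCII-positive cells were Gbp2b (3.83), Cbr2 (3.57), Tmem37 (3.54), Saa3 (3.46) and Folr2 (3.36), which stood between 1.65 (Cbr2) and 2.22 (Saa3) with equal weight. When each shared cluster had equal weight, the ratios were 3.09 for C1qa, 1.74 for Mertk, 1.59 for Ms4a7, 1.43 for Cd63, 0.95 for Ctsd and 0.77 for Lpl, and the Adgre1, Maf, Ccl6 and Lgals3 ratios came inside 1.5-fold, at 0.49, 0.050, 0.32 and 0.36, and Adgre1 was at 0.44 in shallow cells. With all kept cells of every class the Ccl5 ratio was 1.85 and the Cd63 ratio 1.91. T cell-like and NK cell-like cells of clusters 17 and 18 in the MHCII-positive library carried C1qa at 737 CPM, 59.0% of the macrophage-like level there.

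Most measured iron and glycolysis genes were also higher in MHCII-positive cells over the whole class. Fth1, the ferritin heavy chain, was at 10860 and 3768 CPM, Hmox1, heme oxygenase 1, at 565 and 126 CPM, and Blvrb at 879 and 150 CPM, with 9 of 13 genes of the iron and oxidative stress list higher (median 0.99). In glycolysis 11 of 17 genes were higher (median 0.81), with Gapdh at 2485 and 871 CPM and Tpi1 at 574 and 201 CPM. In the hypoxia list 6 of 14 were higher and 8 lay within 1.5-fold (median 0.53, and 0.022 with equal weight per shared cluster), led by Mif at 730 and 180 CPM and Ankrd37 (1.19, and 0.36 with equal weight). Nuclear genes of oxidative phosphorylation had a median of 0.38 with 5 of 19 higher, among them Ndufb8 (0.99) and Cox5a (0.93) but not Cox4i1 (0.15). Matrix remodelling genes had a median of 0.49, with 5 of 10 higher in MHCII-positive cells, such as Timp2 at 208 and 36.9 CPM, and 2 higher in MHCII-negative cells, Mmp8 among them, while Tgfbi (-0.39) lay within 1.5-fold. With equal weight the iron and glycolysis medians were 0.16 and 0.14, and the ratios were 1.02 for Blvrb, 0.61 for Hmox1, 0.59 for Fth1, 0.73 for Gapdh, 0.63 for Tpi1 and 0.83 for Mif, against 2.56, 2.16, 1.53, 1.51, 1.52 and 2.02 over the whole class, and Timp2 was at 1.36 with equal weight. In shallow cells the oxidative phosphorylation median was 1.20, with Cox4i1 at 1.27, the matrix median 0.011, with Tgfbi at -0.80, and the hypoxia median 0.089. Within shared clusters the direction varied. The glycolysis median was -0.51 in cluster 2, -0.34 in cluster 7, 0.66 in cluster 6 and 0.83 in cluster 10. The hypoxia median was -1.29 in cluster 2, where 12 of 14 genes were higher in MHCII-negative cells, -0.34 in cluster 7, -0.018 in cluster 3, 1.07 in cluster 6 and 1.09 in cluster 10, and the iron list ran from -0.45 in cluster 2 to 1.34 in cluster 10.

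MHCII-negative macrophage-like cells carried higher levels of genes of recently recruited monocytes. Of 17 genes 13 were higher there and 2 in MHCII-positive cells (median -1.06, below all 10000 random lists). Ccr2, the receptor that brings monocytes out of the marrow, was at 1504 against 759 CPM (log2 ratio -0.99). Ly6c2 was at 1178 against 763 CPM, a ratio (-0.63) that came inside 1.5-fold with TMM scaling, at -0.39. The exceptions were S100a6 (0.68) and Ly6a (2.76), the second named after its value was seen. Genes with the largest ratios toward MHCII-negative cells also included Ace (-4.86), Serpinb2 (-4.85), Chil3 (-3.85), Bcl11a (-3.84), Dgkg (-3.70), Treml4 (-3.63), Sorl1 (-3.31) and Arhgef18 (-3.20). These cells were not of 1 kind. Ace and Treml4 are leading genes of cluster 8 (900 MHCII-negative and 21 MHCII-positive cells). Ly6c2 was at 594 CPM there, below the level of MHCII-positive macrophage-like cells, and Ccr2 at 854 CPM. With equal weight per shared cluster these ratios were smaller, with Serpinb2 at -3.09, Ace at -2.37, Treml4 at -1.01 and Arhgef18 at -0.91, and those of Mmp8, Pglyrp1, Cd177, Hpgd and Cx3cr1 lay between -3.20 and -2.42. Mmp8 is also a neutrophil marker, and neutrophil-like cells were found in the MHCII-negative library alone. The monocyte median was below 0 in all 5 shared clusters, from -1.07 in cluster 10 to -0.34 in cluster 6. With equal weight the list median was -0.62 and the Ccr2, Ly6c2 and S100a6 ratios came inside 1.5-fold, at -0.56, -0.18 and 0.13, and Ly6c2 was at -0.14 in shallow cells.

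The series title speaks of M1-like macrophages, so genes of classical and alternative activation were compared. The classical list did not stand apart over the whole class. In it 5 of 16 genes were higher in MHCII-positive cells and 4 in MHCII-negative cells, and its median of -0.17 was at percentile 42.7 of random lists. Its direction varied by cluster, with a median of -0.76 in cluster 3, where 0 genes were higher in MHCII-positive and 11 in MHCII-negative cells, -0.21 in cluster 2, -0.11 in cluster 7, 0.24 in cluster 6 and 0.23 in cluster 10. Nos2, inducible nitric oxide synthase, was at 79.6 and 17.2 CPM (log2 ratio 2.21, 2.12 to 2.30), and Cd38 at 81.7 and 10.4 CPM (2.97). Cxcl10, an interferon-induced chemokine, was higher in MHCII-negative cells at 658 against 286 CPM, and so were the costimulatory genes Cd80 (-0.71) and Cd86 (-0.66). Cxcl9 (-0.55), Il1b (-0.58), Tnf (0.42) and Cd40 (-0.0091) lay within 1.5-fold. In the alternative list 8 of 14 genes were higher in MHCII-positive and 2 in MHCII-negative cells (median 1.001), with Mrc1 at 420 and 98.2 CPM, Retnla at 212 and 8.96 CPM, Mgl2 at 30.8 and 1.56 CPM and Arg1, arginase 1, at 275 and 107 CPM, while Chil3 went the other way. The alternative median was 0.013 in cluster 2 (3 genes higher each way), -0.039 in cluster 3, 0.26 in cluster 6, 0.37 in cluster 7 and 1.09 in cluster 10, and Mrc1 was at 1.24 in shallow cells. Cd80 and Cd86 came inside 1.5-fold with TMM scaling, at -0.47 and -0.43, and with equal weight per shared cluster, at -0.28 and -0.157. Over the alternatives their lowest ratios were -1.34 and -1.498. Cxcl10 was uneven among clusters, at 1297 CPM in cluster 6 and 2320 CPM in cluster 10 but 34.8 CPM in cluster 5, the largest of the MHCII-negative library. With equal weight per shared cluster Cxcl10 came inside 1.5-fold, at -0.58, and the ratios were 1.35 for Nos2, 1.51 for Cd38, 1.10 for Mrc1 and 1.88 for Mgl2, against 4.31 for Mgl2 over the whole class. The Nos2 value averages ratios below 0 in clusters 2, 3 and 7 (-1.39, -0.75 and -0.20) with 2.44 in cluster 6 and 6.62 in cluster 10. In cluster 10 the MHCII-negative level was 0.802 CPM, so the average leans on few counts. With all kept cells of every class, neutrophil-like cells included, Il1b was higher in MHCII-negative cells at -0.82. Tnf passed 1.5-fold with TMM scaling (0.66) and in shallow cells (0.69), where Cd40 (-0.71) and Il1b (-0.83) did too, and Cxcl9 did so at 5000 UMIs or more (-0.60).

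**Figure D2:**
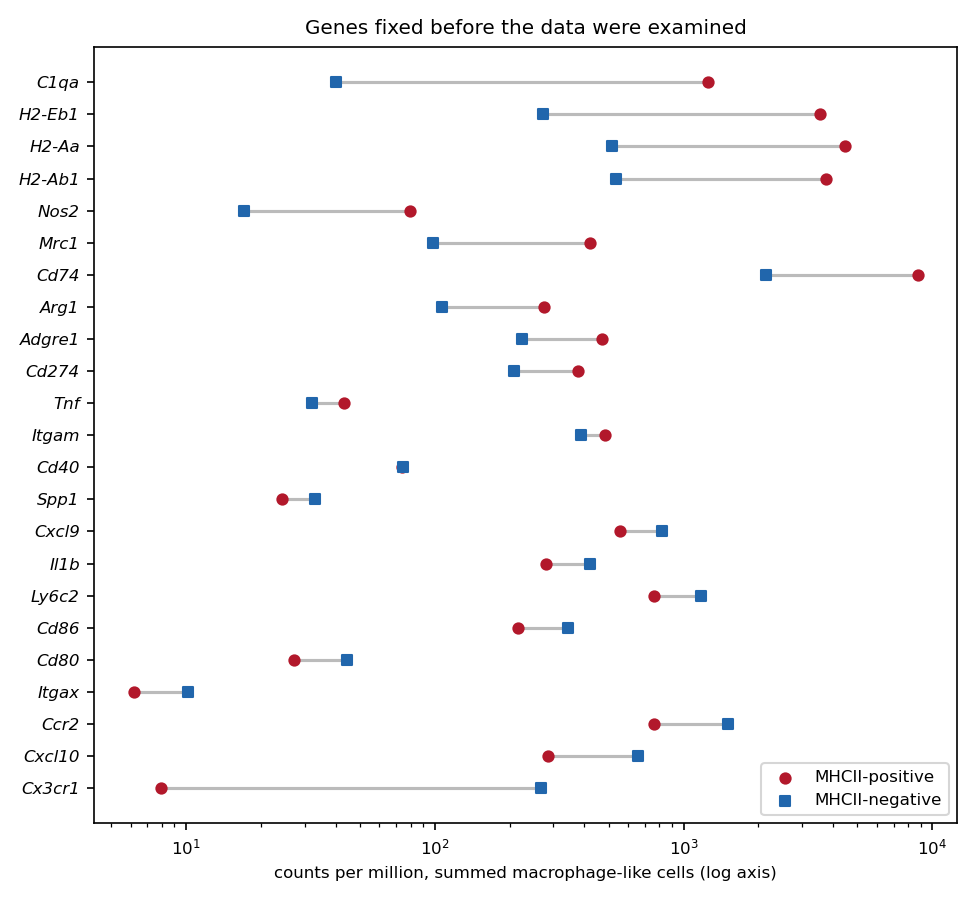
CPM of the summed macrophage-like cells of each library (x axis, log scale) for genes fixed before the data were examined (y axis), with circles for the MHCII-positive and squares for the MHCII-negative library. C1qa (1249 and 40.0 CPM) and Cx3cr1 (7.93 and 268 CPM) lie farthest apart.

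Interferon and NF-kB lists lay inside the range of random lists. The interferon-gamma list had 6 of 23 genes higher in MHCII-positive and 4 in MHCII-negative cells (median -0.19), with Gbp2 at 434 and 634 CPM and Upp1 at 105 and 36.2 CPM. The type I interferon list had a median of -0.38 (percentile 3.1) with 8 of 21 higher in MHCII-negative cells, such as Usp18 (-1.31) and Isg20 (-0.88), and 2 higher in MHCII-positive cells, while Ifi204 (-0.36) lay within 1.5-fold. The NF-kB and inflammasome list had a median of -0.27, with 6 of 19 higher in MHCII-negative cells, and Sod2 (1.31) among the 2 higher in MHCII-positive cells. Cd274, which encodes the inhibitory ligand PD-L1, was at 376 and 208 CPM (0.85). Costimulatory and inhibitory ligands (median -0.089) had 4 of 15 higher in MHCII-positive cells, among them Siglec1 (1.82), and 5 in MHCII-negative cells, among them Havcr2 (-1.71), with Lilrb4a (-0.29) within 1.5-fold. With equal weight per shared cluster Havcr2 turned to 0.35, and Usp18 (-0.50), Sod2 (0.40) and Cd274 (0.24) came inside 1.5-fold. TMM scaling turned the medians of the classical, interferon-gamma and costimulatory lists above 0, to 0.062, 0.038 and 0.14. In cluster 3 the interferon-gamma median was -0.61, with 13 of 23 genes higher in MHCII-negative cells, and the NF-kB median -0.63, with 11 of 19. In shallow cells the interferon-gamma and type I interferon medians were above 0, at 0.33 and 0.23, Isg20 turned to 0.63, Cd274 came inside 1.5-fold at 0.48, and Lilrb4a passed it at -0.76.

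The remaining lists were of receptors, metabolism, stress and the cell cycle. Among chemokine receptors (median -0.036, 0.19 with TMM scaling and -0.55 with equal weight) Cx3cr1, Ccr2 and Cxcr4 (-1.56) were higher in MHCII-negative cells, and 2 of 7 genes were higher in MHCII-positive cells. The arginine list had a median of 0.058, with 3 of 9 higher in MHCII-positive and 1 in MHCII-negative cells. Its median was 0.54 with TMM scaling and 0.80 at a floor of 20 CPM, where 6 genes were measured. In the integrated stress list, with 5 genes measured (median 0.46), 2 were higher in MHCII-positive cells, while Nupr1 (0.46) and Atf4 (-0.35) lay within 1.5-fold. The stress median was 0.10 with equal weight, 0.071 with all kept cells of every class and 0.034 at a floor of 1 CPM. The cell cycle list had a median of 0.75, above the range of random lists, with 6 of 11 higher in MHCII-positive cells, such as Tubb5 (1.27), and 2 in MHCII-negative cells, Hist1h1b (-1.64) and Hmgb2 (-0.86). Immediate early and heat shock genes, which respond to tissue dissociation, had a median of -0.37, with 5 of 16 higher in MHCII-negative cells, among them Ier2 (-1.05) and Hspa1a (-0.85), and 2 in MHCII-positive cells, while Fos (-0.13) lay within 1.5-fold. Of integrin and secreted genes fixed for report, Itgam (0.31) and Spp1 (-0.44) lay within 1.5-fold and Itgax (-0.73) was higher in MHCII-negative cells. With equal weight per shared cluster Itgam turned to -0.27, and its ratio ran from -1.13 in cluster 2 to 0.40 in cluster 10. The cell cycle median turned to -0.24 at a floor of 20 CPM, where 4 genes were measured, Itgax turned to 0.71 and Hmgb2 to 0.010 with equal weight per shared cluster, and TMM scaling brought Itgax inside 1.5-fold at -0.50. In shallow cells Hmgb2 turned to 0.23, Spp1 passed 1.5-fold at -1.26 and the immediate early median was -0.0052, and Nupr1 passed 1.5-fold with TMM scaling at 0.69. Equal weight also brought Cxcr4 (-0.55), Ier2 (-0.34) and Hspa1a (-0.49) inside 1.5-fold.

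Within clusters that held at least 100 cells of each library, C1qa was higher in MHCII-positive cells of clusters 2, 3, 6, 7 and 10, with log2 ratios from 1.86 to 5.60. In clusters 6 and 7 the MHCII-positive level was 163 and 776 CPM. T cell-like and NK cell-like cells of that library held 737 CPM, so a difference in background between the libraries was not separated from these ratios. H2-Ab1 was higher in the same clusters with ratios from 2.05 to 3.46. Cx3cr1 was lower in MHCII-positive cells of all 5, from -5.68 in cluster 10 to -0.69 in cluster 7. Nos2 and Arg1 did not keep 1 direction. In cluster 6 Nos2 was at 77.3 CPM in MHCII-positive and 14.2 CPM in MHCII-negative cells, and Arg1 at 109 and 14.4 CPM. In cluster 2 both were higher in the 143 MHCII-negative cells, with log2 ratios of -1.39 for Nos2 and -2.46 for Arg1, and in cluster 3, with 109 MHCII-negative cells, the ratios were -0.75 and -0.65. Arg1 is a leading gene of cluster 2 and Nos2 of cluster 3, and whether this affects these values was not tested. In cluster 7 the Nos2 interval, -0.93 to 0.62, included equality.

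**Figure D3:**
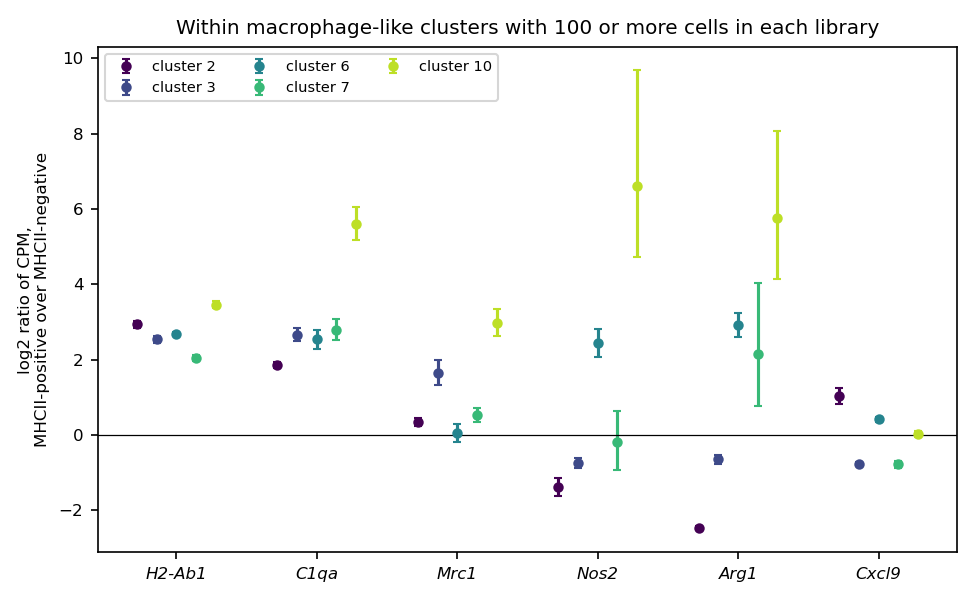
Log2 ratio of CPM (MHCII-positive over MHCII-negative, y axis) of 6 genes (x axis) within each shared cluster, with bars for 95% counting intervals. H2-Ab1 and C1qa lie above 0 in all 5 clusters, and Nos2 lies at -1.39 in cluster 2 and 6.62 in cluster 10.

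The share of cells with a UMI was compared at a fixed 2000 UMIs per cell, in 17401 MHCII-positive and 5800 MHCII-negative macrophage-like cells (8575 and 217 shallower cells left out). H2-Ab1 was found in 99.4% of MHCII-positive and 36.9% of MHCII-negative macrophage-like cells, and in 99.3% and 56.5% without thinning. C1qa was found in 71.4% and 2.40%, and in 77.4% and 5.10% without thinning. Nos2 was found in 11.3% of MHCII-positive cells (10.8 to 11.7) and 1.38% of MHCII-negative cells (1.10 to 1.71), and in 17.02% and 2.78% without thinning. The median depths of these cells before thinning were 4321 and 10692 UMIs.

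Cells that should lack macrophage genes gave the background of these shares. The T cell-like class of the MHCII-positive library was not used whole, because 229 of its 444 cells were of cluster 15, which carried a macrophage profile. Cluster 17 was taken on its own, a split chosen after seeing the data. In the MHCII-positive library Nos2 was found in 14 of 144 cells of T cell-like cluster 17 (9.72%, 5.42 to 15.8) and in 9 of 47 NK cell-like cells (19.1%, 9.15 to 33.3), with median depths of 3331.5 and 4004 UMIs. Cxcl9 was found in 44.3% of macrophage-like cells against 54.2% and 44.7% of these cells, and Il1b in 32.2% against 29.2% (21.9 to 37.3) and 21.3% (10.7 to 35.7). The Nos2 and Cxcl9 shares of the MHCII-positive library lay at or below the share in NK cell-like cells. Over the whole class these shares do not tell how many cells express the genes. Il1b lay inside both background intervals. By level, Nos2 was at 57.8 CPM in T cell-like and NK cell-like cells of that library. MHCII-positive cells of clusters 3, 6 and 10 held 193, 77.3 and 79.1 CPM. Those of clusters 2 and 7 held 34.5 and 14.9 CPM, so the background was not even, though depth was not matched. Nos2 is a leading gene of cluster 3, which was formed on these same counts. Its level there partly restates how the cluster was made, so it does not decide whether evenly spread free RNA is its only source. C1qa was found in 61.1% of cluster 17 (52.6 to 69.1) and 76.6% of NK cell-like cells, and H2-Ab1 in 87.5% and 97.9%. Arg1 was found in 25.8% of macrophage-like cells, 14.6% of cluster 17 (9.26 to 21.4) and 55.3% of NK cell-like cells (40.1 to 69.8), so the background was not alike in both. In the MHCII-negative library, neutrophil-like cells (median 4293 UMIs) carried Nos2 in 0 of 189 cells, which allows up to 1.59%, C1qa in 3.17% and H2-Ab1 in 16.9%. The C1qa and Nos2 shares of MHCII-negative macrophage-like cells are therefore at or under what neutrophil-like cells allow, and the H2-Ab1 share is above theirs. By level this background was uneven. Neutrophil-like cells held C1qa and Nos2 at 51.3 and 8.45 CPM, and 40 T cell-like and NK cell-like cells at 1.93 CPM each. MHCII-negative macrophage-like cells held 509 and 90.3 CPM in cluster 2 and 181 and 325 CPM in cluster 3. C1qb and C1qc are leading genes of cluster 2 and Nos2 of cluster 3. The C1qa level in cluster 2 and the Nos2 level in cluster 3 thus partly restate how the clusters were formed. C1qa in cluster 3 and Nos2 in cluster 2 are not leading genes there. Their levels argue against evenly spread free RNA as their only source in those clusters. In clusters 6, 7 and 10 the C1qa levels were 28.1, 112 and 19.3 CPM. Cluster 5 (2033 MHCII-negative and 16 MHCII-positive cells) held C1qa at 1.05 CPM and Nos2 at 0.789 CPM. Evenly spread free RNA would reach that cluster too. Its C1qa level therefore argues against such RNA as the only source of C1qa in clusters 6, 7 and 10. Uneven free RNA and doublets stay open there, and cluster 5 was formed on these same counts.

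**Figure D4:**
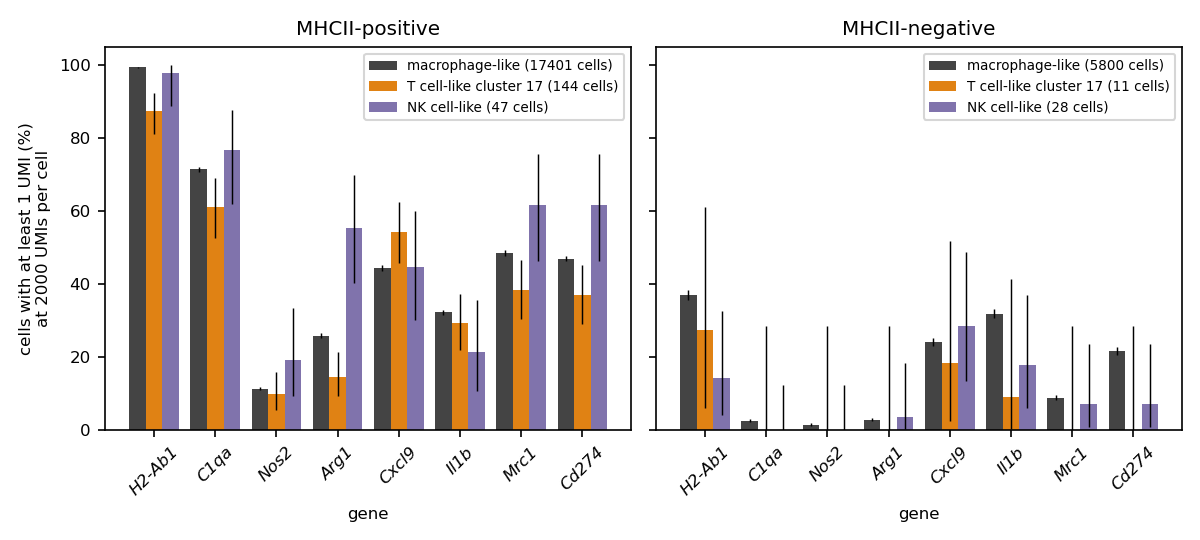
Share of cells with at least 1 UMI at 2000 UMIs per cell (y axis, percent) of 8 genes (x axis) in macrophage-like, T cell-like (cluster 17) and NK cell-like cells of each library, with bars for exact binomial 95% intervals. In the MHCII-positive library Nos2 stands at 11.3% of macrophage-like, 9.72% of cluster 17 and 19.1% of NK cell-like cells.

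Nos2 and MHC class II UMIs were set side by side in the same cells. In the MHCII-negative library Nos2 was found in 54 of 2779 cells with a UMI of H2-Aa, H2-Ab1 or H2-Eb1 (1.94%, 1.46 to 2.53) and in 26 of 3021 cells without one (0.861%, 0.563 to 1.26). With at least 3 MHC class II UMIs required, the shares were 1.71% and 1.25%, with overlapping intervals, and at 4000 UMIs per cell they were 2.99% and 1.30%, with intervals apart. Both sides lie near the limit that 0 of 189 neutrophil-like cells allows. In the MHCII-positive library 1 cell of 17401 lacked MHC class II UMIs, so the comparison by 1 UMI cannot be made there. With at least 3 MHC class II UMIs required at 1000 UMIs per cell, Nos2 was found in 6.87% of cells that had them (6.56 to 7.19). It was found in 22 of 363 cells with fewer (6.06%, 3.84 to 9.03).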

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

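Classes outside the macrophage comparison were looked at because the sort aimed at macrophages, and each had more cells than a count of 0 allows. In the MHCII-positive library these were dendritic cell-like (1.09%), T cell or T lymphoma-like (1.64%), NK cell-like (0.218%) and erythroid-like cells (1.16%), whose cluster 13 carried haemoglobin genes over a macrophage profile, with Lyz2 at 8779 CPM and C1qa at 1094 CPM. In the MHCII-negative library they were dendritic cell-like (0.140%), neutrophil-like (3.45%), mast cell or basophil-like (1.07%), T cell or T lymphoma-like (0.683%), NK cell-like (0.435%) and unnamed cells (0.792%). The T cell or T lymphoma-like shares are listed per library and not compared. Of the 444 MHCII-positive cells so named, 229 were of cluster 15, with a macrophage profile. Of the 44 MHCII-negative ones, 22 were of cluster 21, which has no secure name. Of the tests below, those on whole tumour cells and on evenly spread RNA of cluster 21 genes were chosen only after the result was seen, in place of earlier tests whose outcome was known, as were the condition on the size and name of cluster 21, the correction for dilution and the split of clusters 17 and 18.

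T cell-like and NK cell-like cells of the MHCII-positive library (clusters 17 and 18) carried macrophage transcripts, and the UMI share of C1qa, C1qb, C1qc, Lyz2, Apoe, Csf1r, Mrc1, Lpl and Ctsd in the median such cell was 78.0% of that in the median macrophage-like cell, against 6.90% in the MHCII-negative library. Free RNA in all droplets was set to need a 10th percentile of at least 20% and doublets one under 5%, and the 10th percentile was 13.9%, between both limits, so free RNA and doublets cannot be told apart. Doublets, as cells with the macrophage genes, were also set to hold more UMIs than macrophage-like cells. Over all cells the median was 2778 against 2841. It was 2528 in cluster 17, which goes against doublets there without excluding them, and 3359 in cluster 18, which meets the condition. Cells with and without the macrophage genes were not parted for this. By cluster the 10th percentile was 10.5% in cluster 17 and 46.2% in cluster 18. The second value does not exclude doublets, because a gate on F4/80 can leave a cluster made of doublets alone. In the MHCII-negative library, however, 28 NK cell-like cells passed the F4/80 gate at a median of 6.62%. The 7 cells of cluster 21 in the MHCII-positive library stood at a median of 3.72%, with a median of 16220 UMIs. That cluster has T lineage transcripts but no secure name. No biological explanation was tested.

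Transcripts that were abundant in cluster 21, such as Trbc2, Tox and Rhox5, appeared in cluster 15 over a macrophage profile, with Lyz2 at 7620 CPM in its MHCII-positive cells against 11180 CPM in the macrophage-like cells of that library. Evenly spread free RNA is argued against by 91 genes of cluster 21 taken in 2 parts, since the 229 cells with the most UMIs of 46 genes (136 of them in cluster 15) held 13.6 times as much of the other 45 genes per UMI as the rest of 26205 cells. Doublets with a whole tumour cell stay open. Cluster 15 had a median of 2320 UMIs, 14.3% of that of cluster 21. Cluster 21, however, has 7 cells in that library. Its leading genes hold 0 T cell markers and 1 mast cell marker against the mean of the other clusters. Against their median they hold 2 and 1, so the name of cluster 21 depends on the reference. Cluster 21 is therefore no secure standard for a tumour cell. The cluster 15 median was also under the 2841 UMIs of macrophage-like cells, which goes against such doublets without excluding them. The 91 genes together stood at 14.1% of their level in cluster 21. Engulfed tumour material may also be a source, and tumour cell fragments stay open with it, as does any biological difference behind the sort, which was not tested. The lysosome list was not raised (median log2 ratio -0.29), which met the limit set in advance against engulfment, but that limit ignored dilution by other RNA: 25 macrophage markers had a median of -0.23, and relative to them the 20 genes stood at -0.065, still under the limit of 0 but by less than their median absolute deviation of 0.121.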

How the results depend on the processing

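All settings named here were planned before the data were examined, except 7 that were chosen after seeing the data. Those 7 are the minimum of 5000 UMIs per cell, the range of 2000 to 4000 UMIs per cell, leaving out clusters 0 and 1, leaving out cluster 0 alone, the class shares without the highest doublet scores, the class shares with leading genes taken against the median of the other clusters, and the background shares of single clusters. No paired analysis was possible because each group holds 1 library and no test was made. Keeping called doublets equals the values as reported, since none were removed, and gives no value of its own. In the MHCII-positive library 1 macrophage-like cell lacked MHC class II UMIs at 2000 UMIs per cell and 0 cells did at 4000, so Nos2 in cells without MHC class II has no value there at 4000.

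The main counts were 964 genes higher in the MHCII-positive and 1672 higher in the MHCII-negative library. TMM scaling turned the balance to 1720 and 946. That scaling multiplies every ratio by 1 factor and moves the median of all compared genes from -0.14 to 0.094, with 9191 genes compared in place of 9204. Equal weight for each shared cluster gave 414 and 534 genes, of which 325 and 426 are the same genes as in the main counts, and 3 were called in the opposite direction. A limit of 2-fold gave 430 and 677, a floor of 1 CPM 1482 and 2528, and a floor of 20 CPM 607 and 1043, all by construction. Without cluster 0 the counts were 972 and 1657, with 949 and 1628 genes the same as in the main counts. Only cells with 2000 to 4000 UMIs gave 1875 and 3449, with 726 and 1448 genes the same as in the main counts, 11 called in the opposite direction and a median of all compared genes of -0.31. These cells differ in more than depth, since 337 of the 608 MHCII-negative ones were of cluster 9, and the cause was not tested. The other alternatives stayed within 1.5 times of the main counts.

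The share of monocyte/macrophage-like cells, MHCII-positive, was 94.7% at Leiden resolution 0.5, 94.7% at resolution 2, 96.2% with the stricter filter and 95.3% without the highest doublet scores. The share of monocyte/macrophage-like cells, MHCII-negative, was 82.8% at resolution 0.5, 87.6% at resolution 2, 88.0% with another seed, 95.01% with the stricter filter and 94.2% with leading genes taken against the median. The cause was not tested.

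Of the 24 lists, 18 kept the sign of their median under all alternatives. The cell cycle list was the only one with a median past 1.5-fold that turned, to -0.24 at a floor of 20 CPM, where 4 of its genes were measured in place of 11. Median log2 ratios outside the counting interval of the main value are given by setting, with lists by short names. TMM scaling gave MHC class II 2.11, MHC class I 0.58, M1-like activation 0.062, M2-like activation 1.23, interferon-gamma 0.038, type I interferon -0.15, NF-kB targets -0.043, chemokine ligands 2.04, chemokine receptors 0.19, costimulation 0.14, arginine metabolism 0.54, glycolysis 1.04, hypoxia 0.76, respiration 0.61, complement 2.63, lysosome 0.74, lipid 0.91, monocyte -0.83, mature macrophage 1.48, matrix remodelling 0.72, iron 1.22, stress response 0.69, cell cycle 0.99 and immediate early -0.14. Totals without mitochondrial, ribosomal and the 50 most abundant genes gave MHC class II 1.74, MHC class I 0.37, chemokine ligands 1.59, costimulation -0.068, arginine metabolism 0.33, glycolysis 0.83, lysosome 0.67, lipid 0.79, monocyte -1.04 and immediate early -0.34. Equal weight for each shared cluster gave MHC class II 1.96, MHC class I 0.17, M1-like activation -0.020, M2-like activation 0.78, interferon-gamma -0.24, type I interferon -0.15, chemokine ligands 1.02, chemokine receptors -0.55, glycolysis 0.14, hypoxia 0.022, respiration 0.28, complement 1.08, lysosome 0.30, lipid 0.42, monocyte -0.62, mature macrophage 0.56, matrix remodelling 0.23, iron 0.16, stress response 0.10, cell cycle 0.21 and immediate early -0.13. A floor of 1 CPM gave MHC class II 1.43, M1-like activation -0.0091, M2-like activation 1.30, chemokine ligands 1.57, costimulation -0.049, arginine metabolism 0.56, lysosome 0.65, lipid 0.77, mature macrophage 1.60, matrix remodelling 0.042, stress response 0.034 and cell cycle 0.88. A floor of 20 CPM gave MHC class II 2.03, costimulation -0.049, arginine metabolism 0.80, hypoxia 0.74, lysosome 0.65, lipid 0.97, mature macrophage 1.16, iron 1.19, stress response 0.056 and cell cycle -0.24. The stricter cell filter gave MHC class I 0.37, glycolysis 0.84, lysosome 0.54, lipid 0.71, monocyte -1.03 and mature macrophage 1.22. All barcodes without a filter gave MHC class II 1.97, M1-like activation -0.38, chemokine ligands 1.67, chemokine receptors -0.13, glycolysis 0.78, complement 2.20, lysosome 0.53, lipid 0.70, monocyte -1.02, matrix remodelling 0.022 and stress response 0.070. All kept cells of every class gave M1-like activation -0.40, chemokine ligands 1.66, chemokine receptors -0.14, glycolysis 0.79, complement 2.19, lysosome 0.53, lipid 0.70, monocyte -1.02, matrix remodelling 0.015, stress response 0.071 and immediate early -0.38. Thinning to 2000 UMIs per cell gave M1-like activation -0.11, interferon-gamma -0.046, chemokine ligands 2.08, chemokine receptors -0.095, arginine metabolism 0.30, glycolysis 0.91, respiration 0.44, complement 2.54, lysosome 0.53, lipid 0.76, mature macrophage 1.32, matrix remodelling 0.41, iron 1.21, stress response 0.42 and cell cycle 0.35. The mean of per-cell CPM gave interferon-gamma -0.018, chemokine ligands 2.08, costimulation -0.15, glycolysis 0.85, respiration 0.46, complement 2.61, lysosome 0.44, lipid 0.71, monocyte -1.13, mature macrophage 1.39, matrix remodelling 0.42, iron 1.06, stress response 0.41 and immediate early -0.38. Removal of the highest doublet scores gave chemokine ligands 1.85, costimulation -0.12, arginine metabolism 0.33 and lipid 0.83. Only cells with at least 5000 UMIs gave MHC class II 1.96, MHC class I 0.41, M1-like activation -0.22, costimulation -0.045, glycolysis 0.88, respiration 0.41, complement 2.36, lysosome 0.57, lipid 0.75, mature macrophage 1.19 and immediate early -0.39. Only cells with 2000 to 4000 UMIs gave MHC class II 1.58, MHC class I 0.027, M2-like activation 1.22, interferon-gamma 0.33, type I interferon 0.23, NF-kB targets -0.33, chemokine ligands 2.26, chemokine receptors -0.49, costimulation -0.56, arginine metabolism 0.57, glycolysis 1.45, hypoxia 0.089, respiration 1.20, complement 1.92, lysosome 0.48, lipid 0.45, monocyte -1.13, mature macrophage 1.75, matrix remodelling 0.011, iron 1.45, stress response 0.53, cell cycle 0.53 and immediate early -0.0052. Leaving out cluster 0 gave MHC class I 0.36, arginine metabolism 0.35, glycolysis 0.84, lysosome 0.52 and lipid 0.70. Leaving out clusters 0 and 1 gave MHC class II 1.97, MHC class I 0.39, NF-kB targets -0.21, arginine metabolism 0.41, glycolysis 0.89, respiration 0.41, complement 2.36, lysosome 0.54, lipid 0.76, monocyte -1.03, mature macrophage 1.16, matrix remodelling 0.58 and iron 1.06. The cause of these shifts was not tested, except that TMM multiplies every ratio by 1 factor.

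Of 76 named genes called by the size rule, 24 came inside 1.5-fold or changed sign in at least 1 of 13 alternatives. A change of sign occurred for 4, with equal weight for each shared cluster for Itgax (0.71), Havcr2 (0.35) and Hmgb2 (0.010), and in cells of 2000 to 4000 UMIs for Hmgb2 (0.23) and Isg20 (0.63). In the other direction, Gbp2, within 1.5-fold in the main comparison, stood at -0.88 with equal weight, and Spp1 at -0.62 with thinning to 2000 UMIs. The cause was not tested. Few counts limit some values within clusters: Nos2 stood at 0.802 CPM in 216 MHCII-negative cells of cluster 10, and its ratio there had a counting interval from 4.73 to 9.69 on the log2 scale.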

Other observations

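C1q, Ccl8 and Mrc1 were lower and Chil3, Cd177 and Cx3cr1 higher in MHCII-negative macrophage-like cells (median of 6 signed log2 ratios 5.02), and the tests on depth and neutrophils were chosen after the result was seen, the depth test in place of earlier ones whose outcome was known and with its genes parted once their values were known. For C1qa, Chil3, Cd177 and Cx3cr1 a difference in UMIs per cell is argued against. Cells of 2000 to 4000 UMIs were set over cells of 8000 or more, within either library and with or without cluster 9. In the direction of the gene's log2 ratio between the libraries they showed at most 8.51% of it (Chil3). The largest shift in the opposite direction was -25.9% for C1qa in the MHCII-negative library, and -7.9% there without cluster 9. For Ccl8 and Mrc1 depth stays open, with 70.0% and 48.9% in the MHCII-negative library (87.0% and 31.5% without cluster 9, in 271 shallow cells). In the MHCII-positive library Ccl8 and Mrc1 stood at -4.12% and 4.35%. Neutrophils are argued against in cluster 5, where the higher of S100a8 and S100a9 was at 0.0510% of the neutrophil-like level while Cd177 was at 180.0%. A candidate explanation, as a hypothesis, is a maturation that goes with MHC class II, since MHCII-negative cells with an MHC class II UMI, over those without at equal depth, had log2 ratios from 1.5 (C1qa) to 1.87 (Mrc1) for C1qa, C1qb, C1qc and Mrc1 and of -0.68, -0.65 and -0.48 for Chil3, Cd177 and Cx3cr1 (signed median 1.5). Cells of the MHCII-positive fraction among them would give the same signs for all 7 genes and free RNA for the first 4, which set the median, so the test does not separate maturation from either.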
